A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

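Total RNA from budding yeast (Saccharomyces cerevisiae) had been made into biotinylated cRNA and hybridized to Affymetrix yeast expression arrays, 1 array per sample, per the labels. The 11 arrays comprised a time course of 6 and a strain set of 5. In the time course, a strain with PAF1 under the tetracycline-regulated TetO2 promoter was sampled 0, 2, 4, 5, 6 and 8 h after doxycycline, which represses that promoter, with 1 array per time. The strain set held 2 wild type arrays, 2 paf1 deletion arrays and 1 ctr9 deletion array. Nothing in the labels said whether replicates came from separate cultures. The p-values of single probe sets therefore measured the spread between arrays, in the time course the spread about a fitted line.

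The values were taken as deposited. The 6 time course columns held a linear signal intensity per probe set, which the authors had scaled to 1 common level, since the 2% trimmed mean was about 500 on each array. The 5 strain columns held, as deposited, a score per probe set bounded at -10 and 10 whose scale was not stated. Across probe sets the score followed the signal of the other arrays (Spearman correlation 0.922) but not among the 10% of probe sets with the highest signals, where the correlation was -0.254. A score difference is therefore not a fold change, and a change in an abundant transcript can be compressed. The software, its version and the background and scaling steps were not given in the sources used here.

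The table held 9335 probe sets, of which 60 were controls and were left out of the tests. Exactly 1 gene was listed for 6504 probe sets, several genes for 328 and none for 2443. The 1-gene probe sets covered 5656 genes, 315 of them with several probe sets, and gene lists used the probe set with the highest mean. Gene names, neighbours and chromosome ends were taken from the RefSeq annotation of assembly R64. The array build was not named in the labels.

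The design written before the data were examined had assumed log2 signals on all 11 arrays, and this did not hold for the strain set. Scores were therefore analysed without a logarithm, and signals under the 10th percentile of all values (5.6) were set to it before log2. Probe sets under the 30th percentile of the mean were left out, separately for each kind of value, which kept 6493 for scores (mean score from 2.84) and 6492 for signals (mean signal from 34.6), with 6104 in both. The joint fit of all 11 arrays, the comparison of the 0 h array with wild type, and the floor, the pseudocount and the 2-fold minimum for scores were planned but left out, because scores and signals cannot be placed on 1 scale.

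Linear models were fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. The strain fit gave 3 comparisons, paf1 deletion with wild type, ctr9 deletion with wild type and paf1 deletion with ctr9 deletion. It had 2 residual degrees of freedom, and the lone ctr9 array was assumed to vary like the replicated groups. The time course fit estimated a slope in log2 signal per hour over 6 arrays with 4 residual degrees of freedom, and single times were not tested. All tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Replicate numbers were not used as pairs.

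Before the data were examined, 35 gene lists were fixed, and 32 of them had at least 5 tested members in each comparison. They covered the Paf1 complex, transcription elongation, RNA 3' ends and small nuclear and nucleolar RNAs, translation and ribosome production, stress, metabolism, cell cycle, cell wall, mating and strain markers, chromosome ends, and 2 transcripts that the study had followed up, SDA1 and MAK21. Lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, each adjusted over the 32 lists. At the preset correlation camera compares the genes of a list with the other genes, the correlation being assumed. Such a p-value does not measure the spread between arrays and can be very small with few arrays. Smaller lists were described by values only. List medians at each time were placed among 10000 random lists of the same size matched on signal.

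Genes were named by a rule fixed before the data were examined. It took PAF1, CTR9, CDC73, RTF1 and LEO1, the 10 largest changes in each direction among 1-gene probe sets past the threshold (5 for the comparison of the deletions, filled up by smallest p where too few passed), 2 to 4 members per list described, 5 early responders in each direction, and SDA1 and MAK21. For the paf1 deletion, replicates also had to be non-overlapping.

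The responders of the paf1 deletion were followed in the time course by the earliest time from which that array and all later ones differed from 0 h by at least 1.5-fold in the direction of the deletion. This was early at 2 or 4 h, middle at 5 or 6 h and late at 8 h. Correlations were computed across probe sets, which are not independent replicates, and carry no p-value. The deletions share wild type arrays, so their correlation and the count of shared directions were set beside those of 100 simulated data sets of unchanged groups with the same sharing.

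The fits were tested on simulated data with the array numbers and spread of the study. Score changes of 1, 2, 3 and 4 were recovered in 4%, 30%, 90% and 96% of 50 changed probe sets each. For slopes of 0.1, 0.2, 0.3 and 0.4 log2 per hour the shares were 4%, 28%, 86% and 86%. Unchanged probe sets were called 3 times of 6293 in the paf1 comparison, 0 times of 6493 in the ctr9 comparison and 4 times of 6292 in the time course. A list of 56 genes shifted by 0.5 score passed with the preset correlation (camera adjusted p = 7.8e-09) and not with an estimated one (adjusted p = 0.503). In the time course a list of 60 genes shifted by 0.05 log2 per hour passed with both (adjusted p = 2.9e-10 and 0.0321).

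Alternatives planned before the data were examined covered the filter, normalization, variance model, minimum change, baseline, time scale, paired replicates and leaving out single replicates or times. Alternatives chosen after seeing the data were the removal of a smooth trend of score with signal, a minimum score difference of 2 with and without the test, leaving out 4 h with 6 h, leaving out single arrays for the correlations and for the first sustained time, quantile normalization for that of the deletions, most settings of the fits for the list counts, a term for the arrays with high spike-in signal, exact permutation of the time order, and the simulated count of shared directions. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.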

Results

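Transcript levels were measured on 11 arrays of 9335 probe sets each, in strains lacking the Paf1 complex subunits Paf1 or Ctr9 and in a strain with PAF1 under a promoter that doxycycline represses. The Paf1 complex travels with RNA polymerase II and acts in histone modification, elongation and the formation of RNA 3' ends. The groups were wild type (2 arrays), paf1 deletion (2), ctr9 deletion (1) and 6 times of doxycycline (1 each), so the number of arrays limited the precision. Median scores of the strain arrays lay between 4.78 and 5.03, and the 28 control probe sets without a target in yeast gave scores from -2.08 to 1.93. Replicates correlated across genes at 0.886 for wild type and 0.891 for the paf1 deletion. Median signals of the time course were 108 to 127, against 5.5 for the controls without a target. Spike-in transcripts, added to the samples as controls, gave 4.34-fold the 0 h signal at 4 h and 3.93-fold at 6 h, but 1.01- to 1.14-fold at the other times. The actin 5' to 3' signal ratio was 5.92% at 4 h and 68.6% to 78.6% on the other arrays.

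PAF1 scored 7.27 and 8.08 in wild type, 1.00 and 0.47 in the paf1 deletion and 6.86 in the ctr9 deletion. It fell by 6.94 in the paf1 deletion (SE 0.59, n = 2 per group, limma adjusted p = 0.000487). CTR9 scored 1.84 and 4.36 in wild type, 3.81 and 4.90 in the paf1 deletion and 0.00 in the ctr9 deletion, a difference of -3.10 from wild type that did not pass (SE 1.14, limma adjusted p = 0.414). PAF1 signal in the TetO2 strain was 272 at 0 h, 119 at 2 h, 139 at 4 h, 165 at 5 h, 184 at 6 h and 166 at 8 h, so its lowest value, 43.7% of 0 h, came at the first time. CTR9 signal went from 66.6 to 48.6 over the 8 h and LEO1 from 553 to 309, neither of which passed in the time course. The other subunits did not pass in the paf1 deletion, with differences of 0.37 for CDC73, 1.33 for RTF1 and 0.35 for LEO1 (limma adjusted p = 0.832, 0.442 and 0.855).

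**Figure D1:**
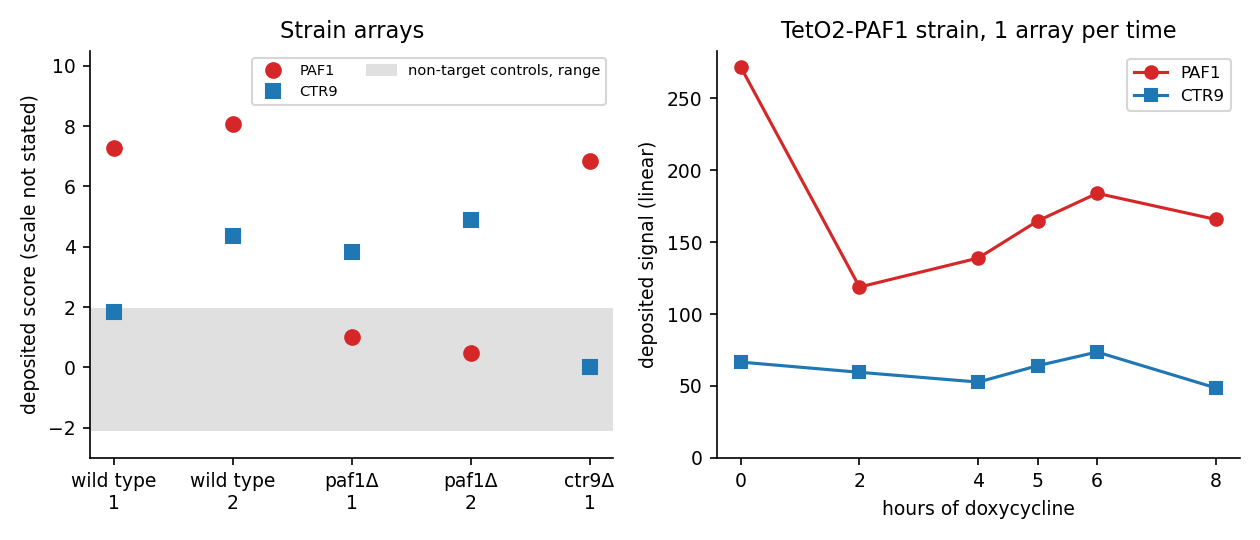
Left, deposited scores of PAF1 and CTR9 on the 5 strain arrays, with the range of the controls without a target in grey; right, their signal against hours of doxycycline, 1 array per time. PAF1 lies in the grey range on both paf1 deletion arrays and at 119 to 184 after the start of doxycycline, from 272 at 0 h.

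The first comparison asked which transcripts differ in cells without Paf1. In the paf1 deletion 111 of 6493 probe sets passed (limma, Benjamini-Hochberg), 73 higher and 38 lower, covering 58 genes higher and 27 lower. The labels gave no strain genotypes, so an effect of losing Paf1 cannot be told apart from a difference in strain background. The largest rise of a probe set with 1 gene was in YNR064C, an epoxide hydrolase gene, by 6.60 score units (SE 0.63, n = 2 per group, limma adjusted p = 0.000754). Its wild type scores, 0.23 and -0.19, lay in the range of controls without a target. HSP26, GLC3 and POT1 were among those that rose beside it, and TRP1, which encodes an enzyme of tryptophan synthesis, had the largest drop, -8.71 (SE 0.68, limma adjusted p = 0.000327), to scores in that range, -0.65 and -1.96. Both wild type scores also lay in it for FIG1, BOP2, POT1, DSE2, PRM3 and YKR104W, and both paf1 deletion scores for PAF1, SRD1 and FLO10, so their differences were taken from a level not above background. The stress-induced genes were shifted up as a group, with 11 of 56 past the threshold, all higher (camera adjusted p = 3.1e-17, but adjusted p = 0.26 with an estimated correlation).

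HSP26, a small heat shock protein gene, went from a mean score of 3.90 to 8.69, a difference of 4.79 (SE 0.62, limma adjusted p = 0.00727). GLC3 and GPH1, which make and break glycogen branches and chains, rose by 4.29 and 3.86, and AMS1, a vacuolar mannosidase gene, by 3.74. Of the 56 tested genes of the environmental stress response 47 were higher, with a median of 1.46, and 28 passed when adjusted over the list alone, all higher (camera adjusted p = 3.1e-17, but adjusted p = 0.26 with an estimated correlation). Heat shock and chaperone genes shared HSP26 as their only member past the threshold. Of 26 tested, 17 were higher and 5 passed adjusted over the list alone (camera adjusted p = 0.00764, but adjusted p = 0.956 with an estimated correlation). The correlations estimated for the stress and heat shock lists, -0.016 and -0.017, lay under the preset 0.01. Correlation between genes therefore does not account for their higher adjusted p in that version of the test.

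SPS19 and POT1, which encode peroxisomal enzymes of fatty acid oxidation, rose by 5.13 (SE 0.71) and 4.67 (SE 0.69). POT1 was the only 1 of 60 respiration and glucose-repressed genes past the threshold, 37 of which were higher and 2 of which passed adjusted over the list alone (camera adjusted p = 0.0124, but adjusted p = 0.988 with an estimated correlation). SPS19 was likewise the only 1 of 5 tested sporulation genes past the threshold, although all 5 were higher and 2 passed adjusted over the list alone (camera adjusted p = 0.0124, but 0.988 with an estimated correlation). The list held 36 genes, of which only these 5 passed the filter. That filter used the mean over wild type and deletion arrays, so a gene can pass through its deletion scores. SPS19, with a wild type mean of 1.895, lay under the limit of 2.84 there. Part of the shared direction can therefore come from the filter. Genes near chromosome ends were higher in 50 of 83 cases, 3 of them past the threshold and 8 adjusted over the list alone (camera adjusted p = 0.0437, but 0.988 with an estimated correlation). The 3 were COS12, at 3.81, YKR104W, at 3.57, and MSC1, which is also on the stress list, at 2.84. Ergosterol synthesis genes were lower in 19 of 26 cases with 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0439, but 0.988 with an estimated correlation). With quantile normalization or after removal of the score trend with signal, the sporulation, chromosome-end and ergosterol lists did not pass. With a filter at the 50th percentile the respiration, chromosome-end and ergosterol lists did not pass, and the sporulation list had too few members.

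Mating and cell wall genes were among the highest single genes without a shift of their lists. FIG1, a membrane protein gene induced by pheromone, rose by 5.18 (SE 0.74), PRM3 by 3.96 and PRM1, which acts in membrane fusion of mating cells, by 3.27. Of the 20 pheromone response genes tested 10 were higher and 10 lower (camera adjusted p = 0.199), and 4 were higher and 1 lower adjusted over the list alone. SAG1, the alpha-agglutinin gene, rose by 4.30, the chitinase gene CTS1 by 1.69, and the cell wall genes DSE2 and PIR3 by 4.22 and 3.84, 4 of 57 cell wall genes, or 5 adjusted over the list alone (camera adjusted p = 0.496). That list had a median of -0.06 but a mean of 0.20. AGP2, a membrane transporter gene, rose by 4.43 (SE 0.59). GSC2, a glucan synthase gene, rose by 5.00 (SE 0.61) in the highest of its 7 probe sets, of which 4 passed and 3, the lowest at 1.14, did not (limma adjusted p = 0.0977 to 0.286). Less is known of SPG4, which rose by 5.17 (SE 1.04), and BOP2, which rose by 4.70 (SE 0.78).

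Lower in the paf1 deletion, besides TRP1 and PAF1, were SRD1, linked to ribosomal RNA processing, by -6.61 (SE 0.61, limma adjusted p = 0.000754), and the flocculin gene FLO10 by -4.75 (SE 0.82). The FLO10 value is the lowest of 6 tested probe sets, of which 3 passed and 3, at -2.84, -1.01 and -0.67, did not (limma adjusted p = 0.0775, 0.506 and 0.731). TDA6 dropped by 4.71 (SE 0.83), the alcohol acetyltransferase gene ATF2 by 4.18 (SE 0.57) and MED11, a Mediator subunit gene, by 4.02 (SE 0.54). MGA1 dropped by 3.99 (SE 0.85), the dolichol kinase gene SEC59 by 3.44 (SE 0.65) and YGL159W by 3.30 (SE 0.71). Single members of other lists were lower too, MET3 of sulfur assimilation at -3.15, the hexose transporter gene HXT4 at -2.98, SYC1 of the 3' end machinery at -2.85, the G1 cyclin gene CLN1 at -2.75 and the RNA polymerase III gene RPC34 at -2.68. The amino acid synthesis list, which holds SNZ1 as a target of the regulator Gcn4, contributed rises in SNZ1, SER3 and ARG3 of 3.09, 2.89 and 2.46. The iron regulon contributed a rise in FIT2 of 2.81. None of these lists was shifted as a group (camera adjusted p = 0.142 for sulfur assimilation, 0.815 for hexose transport, 0.995 for 3' ends, 0.635 for G1 to S genes, 0.311 for polymerases I and III, 0.505 for amino acids and 0.328 for iron).

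RNA processing was of interest because the series concerns a role of the complex after transcription. YDR042C, which lies downstream of the small nucleolar RNA gene SNR47, rose by 4.83 (SE 0.92, n = 2 per group, limma adjusted p = 0.0389). It was 1 of 4 genes fixed for reported read-through from such RNAs, of which TRS31 differed by 0.17 and CTO1 by -0.67, neither passing, and LIN1 was below the filter. Across all 32 tested genes downstream of these RNAs 21 were lower, and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.561). The RNAs named SNR themselves, small nuclear and nucleolar RNAs, were lower in 33 of 46 cases with a median of -0.48, which did not pass (camera adjusted p = 0.176). Ribosome biogenesis genes were lower in 94 of 145 cases, median -0.19, without passing (camera adjusted p = 0.199), and 0 passed adjusted over the list alone. SDA1 and MAK21, which the study selected on these samples and which are thus not independent evidence, differed by 0.30 and -0.38 and did not pass.

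The counts depended on both wild type arrays, since without either of them 0 probe sets passed, and 24 to 56 passed with another filter, normalization or variance model or after removal of the score trend with signal. Limma gave 963 probe sets at an unadjusted p under 0.05, 457 higher and 506 lower, against 325 by chance. A fit of the wild type and paf1 deletion arrays alone gave 89 past the threshold, or 198 with a replicate block. The larger share of higher values, found past the threshold only, was not kept without paf1 deletion replicate 1 and was kept without replicate 2. In those fits 1 array stood for the paf1 deletion, and only the wild type pair gave the spread.

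The second comparison asked whether loss of another subunit changes the same transcripts. In the ctr9 deletion YNR064C rose by 6.34 (SE 0.77, n = 1 against 2, limma adjusted p = 0.0222), and with probe set 3982_at, for which no gene was listed, it was 1 of only 2 past the threshold. Wild type scores of 3982_at, 1.12 and -0.58, lay in the range of controls without a target. Its signal in the TetO2 strain was 9431 to 11420, also at 0 h. Strain genotypes were not in the labels, so a difference of both deletions from wild type cannot be told apart from a difference in strain background. The next genes did not pass. HSP26 differed by 5.01, GSC2 by 5.00 and AGP2 by 4.60 (limma adjusted p = 0.0777 each), the arginine synthesis gene ARG3 by 3.85 (limma adjusted p = 0.0794), and SPS19 by 4.66 (limma adjusted p = 0.116). The GSC2 value is again the highest of 7 probe sets, the others at 1.13 to 4.41.

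Also among the 10 smallest p on the higher side, without passing, were SAG1 at 4.36, PUL3 at 4.30, the amino acid permease gene GAP1 at 3.96 and GOR1 at 3.74. On the lower side, TDA6 differed by -5.22, YKR075C by -4.95, FLO10 by -4.57, TRI1 by -4.19, ADH5 by -3.98 and ATF2 by -3.89. YCL049C, SYC1, TDA2 and YEH1 completed that side at -3.56, -3.36, -2.96 and -2.52. The FLO10 value is the lowest of 6 tested probe sets. The ctr9 deletion scores of TDA6, 1.89, and YCL049C, 1.85, lay in the range of controls without a target, so these differences were taken to a level not above background. The smallest adjusted p on the lower side was 0.0937 in limma.

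As groups, stress-induced genes were higher in 47 of 56 cases with a median of 1.23 (camera adjusted p = 1.9e-12, but adjusted p = 0.359 with an estimated correlation), and 20 were higher adjusted over the list alone. Respiration genes were higher in 50 of 60 cases (camera adjusted p = 0.0038). Mitochondrial ribosomal protein genes were higher in 54 of 67 and the 5 tested sporulation genes in all (camera adjusted p = 0.0212 each). With an estimated correlation each of these lists gave adjusted p = 0.99. The sporulation genes were again those kept by a filter that used the deletion arrays too. RNAs named SNR were lower in 32 of 46 cases with a median of -0.47 (camera adjusted p = 0.0038, but adjusted p = 0.99 with an estimated correlation), and the lowest, SNR52 at -3.75, to a score of 1.43 in the range of controls without a target, and SNR3 at -2.65, did not pass singly. Adjusted over the list alone, 1 respiration and 1 sporulation gene were higher and 0 genes of the mitochondrial ribosomal and SNR lists passed. The sporulation list did not pass without a filter, with quantile normalization or after removal of the score trend with signal, nor the SNR list with a filter at the 50th percentile. Heat shock genes, 15 of 26 higher, did not pass (camera adjusted p = 0.15). SDA1 and MAK21 differed by 0.53 and -0.53. The count of 2 was 0 with another filter, normalization or variance model, and limma gave 626 probe sets at an unadjusted p under 0.05.

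Across the 6493 probe sets the differences of the paf1 and ctr9 deletions from wild type correlated at 0.754 (Pearson) and 0.695 (Spearman). Shared wild type arrays alone gave 0.410 in simulated unchanged groups. With a separate wild type array for each deletion the data gave 0.421 and 0.465. That setting shares no array, so the spread of a shared array cannot raise these 2 values, and 0.410 is not their no-change value. It was not simulated. The observed covariance, 0.748, exceeded the simulated 0.167 by 0.581. Of the 111 probe sets past the threshold in the paf1 deletion, 108 differed in the same direction in the ctr9 deletion. Much of that count comes from shared arrays and selection, since in the simulated unchanged groups the 111 with the smallest p gave a mean of 96.6 and at most 104 in 100 simulations. Their median differences were 1.58 for the paf1 and 0.76 for the ctr9 deletion, in the direction of the former. In the data the higher ones had medians of 3.40 in the paf1 and 3.14 in the ctr9 deletion, and the lower ones -3.08 and -1.83. Genes are not independent replicates, so no p-value belongs to these correlations. A difference in strain background between wild type and both deletions would also add to them, and was not tested.

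**Figure D2:**
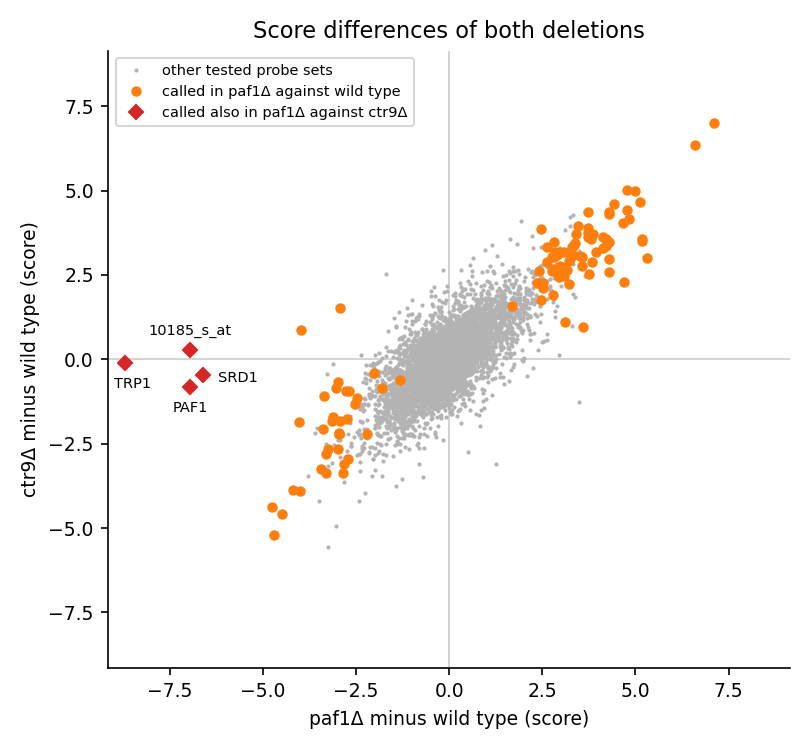
Score difference from wild type of each probe set in the paf1 deletion (horizontal) and the ctr9 deletion (vertical), both against the same 2 wild type arrays. Orange points are the 111 past the threshold in the paf1 deletion, of which 108 lie on the same side of 0 in the ctr9 deletion (96.6 on average in simulated unchanged groups with shared wild type arrays), and red diamonds the 4 that differ between the deletions.

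The direct comparison of the deletions tested the differences between them. Only 4 probe sets passed, all lower in the paf1 deletion than in the ctr9 deletion. TRP1 was lower by -8.59 (SE 0.83, n = 2 against 1, limma adjusted p = 0.00269), probe set 10185_s_at, shared by 4 genes, by -7.25 (SE 0.64, limma adjusted p = 0.00227), and PAF1 and SRD1 by -6.13 each (SE 0.72 and 0.75, limma adjusted p = 0.011 and 0.0126). The ctr9 deletion scores of TRP1 differed from wild type by only -0.12. On the other side nothing passed, with CTR9 at 4.36, TRM3 at 3.28, the phosphate-responsive PHM7 at 2.82, INP54 at 2.34 and BTN2 at 2.25, and the polarity gene SPA2 at -4.46 and the transporter gene YOR1 at -4.23 did not pass either. For TRM3, SPA2 and YOR1 these values came from 1 of 6, 7 and 5 tested probe sets, and the others lay between -2.64 and 2.11.

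Among lists, mitochondrial ribosomal protein genes were lower in the paf1 than in the ctr9 deletion in 51 of 67 cases (camera adjusted p = 0.0202), purine synthesis genes in 16 of 19 and marker genes in 6 of 6 (0.0427 each), of which TRP1 alone passed singly or adjusted over the list alone. With an estimated correlation each gave adjusted p = 1.00. None of the 3 passed after removal of the score trend with signal, and only the mitochondrial list passed with quantile normalization or a filter at the 50th percentile. Limma gave 190 probe sets at an unadjusted p under 0.05, fewer than the 325 due by chance, and without either wild type array 0 passed the threshold.

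The time course asked which transcripts move first after doxycycline is added to the TetO2-PAF1 strain. After 2 h the 145 ribosome biogenesis transcripts had a median of 55.7% of their 0 h signal, and 144 of them were lower, while stress-induced transcripts had a median of 3.11-fold, 58 of 60 being higher. Both changes were already present in the first array after doxycycline, when PAF1 was at 43.7%. The list slopes passed, with ribosome biogenesis lower in 138 of 145 cases at a median of -0.06 log2 per hour (camera adjusted p = 2.8e-20) and stress genes higher in 59 of 60 at 0.16 (camera adjusted p = 1.1e-14). With an estimated correlation each gave adjusted p = 0.596.

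For ribosome biogenesis the median against 0 h was -0.84 log2 at 2 h, -0.35 at 4 h, -0.90 at 5 h, -0.79 at 6 h and -0.59 at 8 h. The 4 h array, with its high spike-in signal and low actin 5' to 3' ratio, stood closest to 0 h. Between 2 h and 8 h 105 of the 145 were higher at 8 h. SDA1, needed for ribosomal subunit assembly and export, had signals of 877, 412, 487, 322, 304 and 348, and MAK21, likewise of ribosome assembly, 712, 409, 465, 291, 235 and 287. They sloped by -0.16 (SE 0.05) and -0.18 (SE 0.05) per hour, did not pass singly (limma adjusted p = 0.549) and are not independent evidence, having been selected by the study on these samples. RRP12 went from 3443 to 1320. The fall rested on the 0 h array: without it 61 of 145 were lower, the median slope was 0.01 although the camera direction stayed down, and the list did not pass (camera adjusted p = 0.984).

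Other lists were shifted down as well. RNA polymerase I and III genes were lower in 17 of 20 cases (camera adjusted p = 0.00021, but adjusted p = 0.596 with an estimated correlation), with RPO31 going from 846 to 403. Without the 0 h array the median slope of this list turned to 0.007, and 13 of 20 were higher at 8 h than at 2 h. Translation factor genes were lower in 25 of 29 (camera adjusted p = 1.1e-05, but 0.596 with an estimated correlation), with TIF4631 going from 896 to 540. Cytosolic ribosomal protein genes were lower in 55 of 80 cases, by a median of only -0.02 per hour (camera adjusted p = 0.000922, but adjusted p = 0.765 with an estimated correlation). Ergosterol synthesis genes were lower in 18 of 25 cases (camera adjusted p = 0.0195, but 0.596 with an estimated correlation). In all 4 lists 0 genes passed adjusted over the list alone. Ribosomal protein and ergosterol genes did not pass with quantile normalization, with a term for the spike-in batch, or with late against early times.

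RNAs named SNR had a median of -0.51 log2 against 0 h at 2 h, -0.26 at 4 h, -0.25 at 5 h, -0.50 at 6 h and -0.67 at 8 h, when 39 of 50 were lower. Their slopes were lower in 39 of 50 cases with a median of -0.05 per hour, and 6 were lower adjusted over the list alone (camera adjusted p = 3.0e-08, but adjusted p = 0.596 with an estimated correlation). The largest changes, which did not pass singly, were in the U1 RNA gene SNR19, from 158 to 27.4, and SNR52, from 131 to 20. Without the 0 h array 29 of 50 were lower and the list still passed (camera adjusted p = 0.0142, but adjusted p = 0.997 with an estimated correlation).

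Stress-induced transcripts were 1.64 log2 above 0 h at 2 h, 1.27 at 4 h, 0.94 at 5 h, 1.65 at 6 h and 1.56 at 8 h. HSP26 had signals of 292, 2057, 2922, 311, 1263 and 1778, with a 5 h value near that at 0 h, and GPH1 134, 575, 780, 138, 588 and 753. Heat shock genes were shifted up in 24 of 26 cases (camera adjusted p = 7.5e-07, but adjusted p = 0.596 with an estimated correlation), HSP82 going from 184 to 2601 and HSP78 from 48.8 to 494. Respiration genes were shifted up in 47 of 59 (camera adjusted p = 3.9e-06, but 0.596 with an estimated correlation), IDH1 of the citric acid cycle going from 291 to 1083. Without the 0 h array stress and heat shock genes did not pass (camera adjusted p = 0.596 each), nor did respiration genes, whose median slope was then -0.002. Mitochondrial ribosomal protein genes were higher in 60 of 67 cases (camera adjusted p = 0.00224), proteasome genes in 32 of 35 (0.00197), iron genes in 22 of 25 (0.0179) and sporulation genes in 4 of 5 (0.0322). With an estimated correlation mitochondrial ribosomal proteins gave adjusted p = 0.876 and the others 0.596, and adjusted over the list alone 2 sporulation genes and 0 of the other lists passed. Mitochondrial ribosomal protein and sporulation genes did not pass with a term for the spike-in batch or with late against early times. Without the 0 h array only 2 of the 14 lists that passed in the time course still did, those of SNR RNAs and chromosome ends.

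Genes near chromosome ends were highest at 8 h. Their median against 0 h was 0.13 log2 at 2 h, 0.27 at 4 h, 0.09 at 5 h, 0.24 at 6 h and 0.45 at 8 h, with 67 of 88 higher and 37 at least 1.5-fold higher at 8 h. HXK1, a hexokinase gene that is also on the stress list, went from 491 to 2560. The slopes were higher in 68 of 88 cases (camera adjusted p = 0.000515, but adjusted p = 0.596 with an estimated correlation), and the list still passed without the 0 h array (camera adjusted p = 0.0142, but adjusted p = 0.997 with an estimated correlation). An exact permutation of the order of the arrays, chosen after seeing the data, gave this list the smallest p, 0.00278 (two-sided), which did not pass after adjustment over 32 lists (adjusted p = 0.0889). The same permutation gave ribosome biogenesis p = 0.224, stress genes p = 0.0958 and RNAs named SNR p = 0.158 (adjusted p = 0.52).

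**Figure D3:**
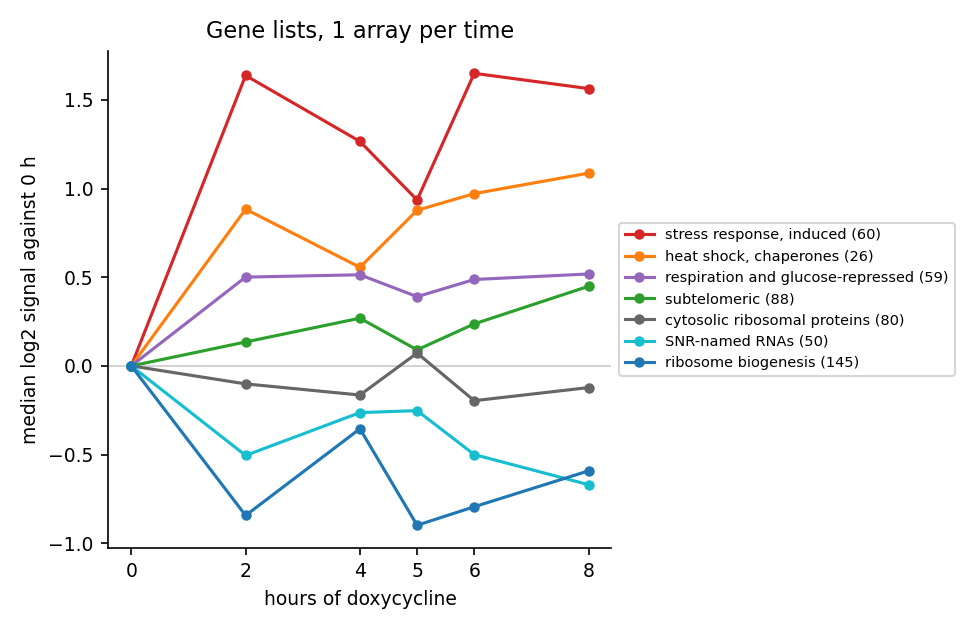
Median log2 signal against 0 h of 7 gene lists by hours of doxycycline, 1 array per time. Ribosome biogenesis is at -0.84 and stress genes are at 1.64 at 2 h, while genes near chromosome ends reach 0.45 at 8 h.

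No single transcript passed in the time course, where limma called 0 of 6492 probe sets with a smallest adjusted p of 0.549 and 563 at an unadjusted p under 0.05. The smallest p on the rising side belonged to the phospholipase gene PLB1, from 664 to 1825, SPS19, from 90.8 to 346, YBR085C-A, SNZ1, the calcineurin subunit gene CNB1, SAG1, CIS1, UGA1, YIR020C and POT1, with slopes of 0.14 to 0.22 log2 per hour. On the falling side, the SNR RNAs SNR19, SNR52, SNR69, SNR17A and SNR48 were joined by BNA7, RRP15, FAS2, YRB30 and NOP56, with slopes of -0.12 to -0.37. FAS2, at -0.37, was 1 of 7 tested probe sets of its gene, the others at -0.52 to 0.01, and CNB1, at 0.19, 1 of 2, the other at 0.07. At least 2-fold different from 0 h were 511 probe sets at 2 h, 896 at 4 h, 522 at 5 h, 630 at 6 h and 638 at 8 h, against 272 between 2 h and 8 h. The 4 h array, with the most, also had the actin 5' to 3' ratio of 5.92% and the lowest mean correlation with the other times, 0.919.

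The last question was how the time course relates to the steady state without Paf1. Across 6104 probe sets the slope per hour and the difference in the paf1 deletion correlated at 0.337 (Pearson) and 0.339 (Spearman), with no array in common, and genes are not independent replicates. Without the 0 h array the Pearson value was 0.141. Of 89 probe sets past the threshold in the deletion and measured in both, 78 moved the same way, 53 of 57 higher and 25 of 32 lower, and 72 did so without the 0 h array.

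Of the 111 deletion responders, 59 reached a sustained 1.5-fold change in the direction of the deletion, against a median of 20 in random lists matched on signal. They were 28 early, against 4 in random lists, 18 middle and 13 late. In the opposite direction 6 changed, against 17 in random lists. All 11 stress-induced genes past the threshold in the deletion were early or middle. Random lists were matched on signal only, so part of the excess can restate the rise of the stress list after doxycycline. PAF1, which doxycycline represses by design, counted as late although its signal was lowest at 2 h. The early ones, 24 higher and 4 lower, included SPS19, from a signal of 90.8 at 0 h to 346 at 8 h, POT1, from 46.7 to 189, SAG1, from 422 to 985, GLC3, from 88.6 to 579, and PUL3, from 53.1 to 158. Lower and early were ATF2, from 224 to 88.4, MHF2, from 240 to 131, and HKR1, from 122.6 to 49.8, the only 3 that had 1 gene. TRP1, at 178 and 170, SRD1, FIG1, PRM1, PRM3 and YDR042C reached no sustained change. The split between early and middle rested in part on the 5 h array, without which 39 were early (8 in random lists) and 7 middle, since genes such as HSP26 and GPH1 were back near their 0 h signal at 5 h alone. The early count was 13 with a 2-fold minimum and 7 with the mean of 0 h and 2 h as baseline, which takes up part of any change at 2 h, each against 1 in random lists.

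**Figure D4:**
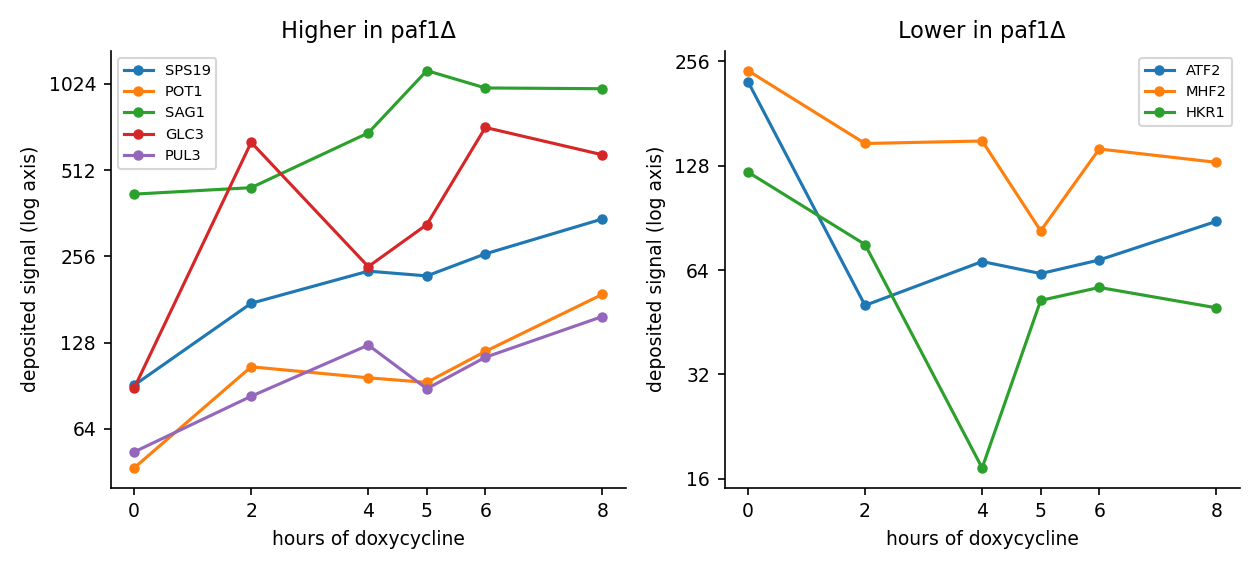
Signal (log axis) by hours of doxycycline, 1 array per time, of early responders that were higher (SPS19, POT1, SAG1, GLC3, PUL3) or lower (ATF2, MHF2, HKR1) in the paf1 deletion. GLC3 goes from 88.6 to 579 and HKR1 from 122.6 to 49.8.

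The remaining lists passed in no comparison. Of the 32 lists tested 16 passed at the preset correlation in at least 1 comparison, and the smallest adjusted p of the other 16 ranged from 0.0561, for amino acid synthesis in the time course, to 0.815. In the paf1 deletion camera gave adjusted p = 0.86 for elongation and chromatin factors, 0.915 for the Paf1 complex, 0.448 for the 5 histone genes, all lower, 0.913 for G2 to M genes, 0.426 for glycolysis, 0.496 for the phosphate regulon and 0.913 for seripauperin and anaerobic genes. Genes of the a mating type gave camera adjusted p = 0.323, with 5 of 6 lower. In the TetO2 strain such transcripts were present, as MFA1 at 7874 at 0 h, a signal that does not bear on the strain arrays. Of the alpha-type genes only SAG1 passed the filter on scores. SDC1 and DOT1, histone methylation genes, had the largest differences among elongation and chromatin factors, -1.88 and -1.68, and did not pass.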

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

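The tests of explanations in this part were chosen only after the results were seen, except the placement among random lists, which was made for every list and time. The comparison of the deletions was planned. A difference between the deletions picked out 4 probe sets whose paf1 deletion score lay under the ctr9 deletion score, namely TRP1 by -8.59, probe set 10185_s_at by -7.25, SRD1 by -6.13 and PAF1, the deleted gene, by -6.13. A signal in control data that no comparison used picked out the spike-in transcripts, at 4.34-fold the 0 h signal at 4 h and 3.93-fold at 6 h.

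TRP1, SRD1 and probe set 10185_s_at were low in the paf1 deletion alone. A wrong strain label on the paf1 deletion arrays was excluded, with a highest PAF1 score of 1.00 on them and a lowest of 6.86 elsewhere. Sequence missing or replaced in the paf1 deletion strain stays open and could account for it, since 6 of 6 scores of the probe sets on these arrays lay in the range of controls without a target. TRP1 was on the fixed list of auxotrophic and marker genes, of which no other tested member passed in the paf1 deletion. A probe set of HIS3, also on that list, was below the filter but scored higher in the paf1 deletion than in wild type. A difference in markers between the strains was not tested, since the labels gave no genotypes. A role of Paf1 that Ctr9 does not share also stays open, as untested, since TRP1, SRD1 and 10185_s_at were picked for a difference between the deletions.

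Ribosome biogenesis transcripts were lower after the start of doxycycline. A batch shown by the spike-ins at 4 h and 6 h was argued against as the cause. Lower than at 0 h were 144, 143 and 139 of the 145 at 2 h, 5 h and 8 h. Without the 4 h and 6 h arrays camera gave adjusted p = 9.4e-16 at the preset correlation, but 0.751 with an estimated one. That test cannot decide, since the correlation estimated for this list over all times was 0.7017. The 0 h array standing apart alone could account for the slope, since without that array the adjusted p was 0.984 (0.997 with an estimated correlation) and 61 of 145 were lower. Loss of PAF1 mRNA cannot be told apart from it, because 105 of 145 transcripts were higher at 8 h than at 2 h while PAF1 signal also went from 119 to 166, and PAF1 itself was lowest at 2 h. Doxycycline itself stays open as well, because no strain without the TetO2 promoter was treated.

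RNAs named SNR were lower over the hours of doxycycline. High spike-in signal at 4 h and 6 h was argued against as the cause, since 42, 37 and 39 of 50 were lower at 2 h, 5 h and 8 h. Without the 4 h and 6 h arrays camera gave adjusted p = 3.9e-07 at the preset correlation, but 0.751 with an estimated one. The 0 h array as the whole cause stays open. Without it camera gave adjusted p = 0.0142 at the preset correlation of 0.01, but 0.997 with an estimated one, and 29 of 50 were lower. That test cannot decide, since the correlation estimated for this list over all times was 0.2475. At 8 h 28 were lower and 22 higher than at 2 h. Most of the median change, -0.51 of -0.67 log2, was there at 2 h. Low signal of the members did not account for the fall, as the 8 h median was at percentile 0 of random lists matched on signal. Exact permutation of the array order gave p = 0.158 (adjusted p = 0.52), and loss of PAF1, whose signal was 119 at 2 h and 166 at 8 h, doxycycline itself and the recovery of short RNAs stay open, as untested.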

How the results depend on the processing

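Chosen after seeing the data were the batch term, leaving out 4 h with 6 h, the removal of the score trend with signal, the score minimum of 2, the exact permutation, leaving out arrays or replicates for the correlations or the first sustained time, quantile normalization for that of the deletions, and for list counts all but an estimated correlation, no filter, and quantile normalization. The others were planned, including leaving out single replicates or times for counts of single probe sets. Of the values of named genes under alternatives, 876 kept their direction and side of the threshold, 42 gained and 89 lost the call, and 15 reversed. For lists these numbers were 279 kept, 62 lost and 4 reversed. The count of 111 for the paf1 deletion became 41 without a filter, 56 with a filter at the 50th percentile, 42 with quantile normalization (28 higher), 39 without the variance trend, 24 after removal of the signal trend (13 higher, against 65.8% of the main count) and 89 with the wild type and paf1 deletion arrays alone, or 198 for these with a replicate block, while the rule without a test gave 328. Replicate numbers do not pair, since their differences correlated at 0.008 between the groups across genes. Leaving out 1 replicate gave 0 to 190 for the paf1 deletion, 0 to 108 for ctr9 (main count 2) and 0 to 11 between the deletions (main count 4). The ctr9 count was 0 without a filter, at the 50th percentile, with quantile normalization, without the variance trend and after removal of the signal trend. Between the deletions 5 passed without a filter (1 higher in the paf1 deletion), 2 at the 50th percentile, with quantile normalization and without the variance trend, and 1 after removal of the signal trend. The time course count stayed 0 throughout. The correlation of the deletions was 0.421 and 0.465 with separate wild type arrays and 0.683 to 0.816 when 1 replicate was left out, and that with the time course was 0.141 without the 0 h array. Early responders were 13 at 2-fold, 7 against the mean of 0 h and 2 h, 39 without the 5 h array, and 9 of the 24 left after removal of the signal trend. Fewer arrays or fewer probe sets lie behind some of these, and for the others the cause was not tested.

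Lists passing in the paf1 deletion numbered 3 at the 50th percentile, with quantile normalization and after removal of the signal trend, and 0 with an estimated correlation. When 1 replicate was left out stress and heat shock genes always passed there, while the respiration, ergosterol, sporulation and chromosome-end lists each lost the call at least once. In the ctr9 deletion they were 3 at the 50th percentile and 0 with an estimated correlation. When 1 replicate was left out stress and respiration genes always passed there, while the mitochondrial ribosomal, sporulation and SNR lists each lost the call at least once. Between the deletions they were 1 at the 50th percentile and with quantile normalization, 0 after removal of the signal trend and with an estimated correlation, and 1 to 5 when a replicate was left out. In the time course they were 3 without the 0 h array and 0 with an estimated correlation or exact permutation. With 5, 6 and 8 h set against 0, 2 and 4 h, the reversed medians were 0.00745 for cytosolic and -0.073 for mitochondrial ribosomal proteins. Without the 0 h array mitochondrial ribosomal proteins were at 0.000982, against the direction of the camera test, and respiration was at -0.00204. The 4 reversals of lists were counted by the direction of the camera test. By median, ribosome biogenesis, at 0.0108, and RNA polymerase I and III genes, at 0.00722, also turned without the 0 h array and were not counted. Genes that never passed also reversed. When 1 replicate was left out the ranges were -0.005 to 2.52 for CTR9 and -0.83 to 0.08 for MAK21 in the paf1 deletion, and -0.18 to 1.52 for RTF1 and -0.17 to 0.47 for LEO1 in the ctr9 deletion. Between the deletions they were -0.31 to 0.24 for CDC73, -0.15 to 1.47 for RTF1 and -0.30 to 0.61 for MAK21, and CDC73 was 0.11 with quantile normalization and 0.12 after removal of the signal trend. In the time course the slope or difference of PAF1 was 0.054, of CTR9 0.045 and of RTF1 -0.099 with late against early times, PAF1 was 0.092 without the 0 h array, and CTR9 was 0.013 and RTF1 -0.016 without the 8 h array. The causes were not tested. The joint fit of 11 arrays, the comparison of the 0 h array with wild type, and a floor, pseudocount or 2-fold minimum for scores were not run, because scores and signals share no scale. Scores near those of controls without a target, such as CTR9 in wild type at 1.84, leave little room for a decrease, and scores at high signal little room for an increase.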

Other observations

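Transcripts encoded in mitochondrial DNA, a group chosen after the values were seen, did not follow the hours of doxycycline. In 6 probe sets of ATP6, COB, COX1 and OLI1, which encode subunits of the respiratory chain and ATP synthase, the median was 101% of 0 h at 2 h, 32.4% at 4 h, 133% at 5 h, 47.4% at 6 h and 36.6% at 8 h. All 6 were lower at 4 h, 6 h and 8 h, and 0 were lower at 5 h. A COX1 probe set had signals of 1822, 2121, 83.5, 3453, 543 and 364. The 4 h and 6 h arrays were also those with high spike-in signal, which the 8 h array did not share, at 1.08-fold the 0 h signal. The 4 h array alone also had the low actin 5' to 3' ratio, 5.92%. Nuclear genes of mitochondrial ribosomal proteins had medians of 0.84 log2 above 0 h at 4 h and -0.01 at 5 h.

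Among marker genes, both probe sets of HIS3 were below the filter and so untested. For 1 of them the scores were -0.69 and -1.82 in wild type, 5.95 and 6.06 in the paf1 deletion and 1.22 in the ctr9 deletion. Its signals were at most 6.7 in the time course. Probe set 3982_at, with no gene listed, scored 1.12 and -0.58 in wild type, 7.27 and 7.47 in the paf1 deletion and 7.28 in the ctr9 deletion, and its signal was 9431 to 11420 across the time course. The 5 h array held the highest signals of FIT2, a cell wall mannoprotein gene of iron uptake, at 1229, and of the pheromone gene MFA1, at 15880. These genes were chosen after their values were seen.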
